A study of Homo sapiens and Homo sapiens
Mus musculus with 24 samples.

How the data were processed

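The series tested MULTI-seq, a way of tagging cells or nuclei with DNA indices on lipid anchors so that many samples can share a droplet run. It lists 24 samples, of which 13 are RNA libraries and 11 are libraries of the sample indices. Per the labels' protocols, cells were lysed in droplets on the 10X Chromium instrument and RNA libraries were made with its 3' chemistry. RNA was measured in a mixture of HEK cells and human mammary epithelial cells (HMECs), in nuclei of a mixture of HEK cells, Jurkat cells and a further cell type, in HMECs from several culture conditions, and in a patient-derived xenograft (PDX) with human metastases and mouse immune cells. The index libraries and the remaining technical-replicate lane of the HMECs (lane 4) were not analysed here, so no cell was assigned to a tagged sample or culture condition.

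The authors deposited 8 matrices of raw counts, 1 whole number per gene row and barcode column, each count being a number of unique molecular identifiers (UMIs). Cell Ranger 2.2 and bcl2fastq 2.19 are named in the submitters' processing notes, as are human and mouse genome builds, without their roles. The deposited counts carried no normalization and no cell filter: each matrix listed every possible barcode. The original HMEC experiment and the cell mixture were each deposited as 1 matrix whose columns formed 3 equal parts, and the nuclei as 1 matrix of 2 equal parts. No part was matched to a lane or to a tagging reagent, so each such matrix counted as 1 sample and its parts were given as values, except in 1 added test of the original HMECs. The matrices were used without gene names or barcode sequences, so rows are given by number and populations are numbered. Marker lists fixed beforehand could not be applied. Human rows lay in the same order in the matrices compared: across rows, Spearman's rho between HMEC lane 1 and the original experiment was 0.940, and it was 0.231 when rows were shifted by 1.

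Barcodes with at least 500 UMIs were kept. Counts were scaled to 10000 per barcode and log-transformed. Clustering used 2000 variable rows, 30 principal components, 15 neighbours and the Leiden method at a resolution of 0.2 (leidenalg 0.10.2). Components were computed with numpy 2.4.6 in Python 3.11.15, and k-means came from scikit-learn 1.9.0. The 3 HMEC technical-replicate lanes were clustered together on odd-numbered rows, with each lane centred. The even-numbered rows were held out, so that rows tested between populations had played no part in defining them. The cell mixture and the human nuclei were each divided into 2 populations by k-means with a fixed seed of 1. A nucleus was called human or mouse where at least 90% of its UMIs lay on rows of that organism, and mixed otherwise. To compare detected rows across depths, each barcode with at least 2000 UMIs was thinned to 2000 UMIs. Doublets were called with Scrublet in scanpy 1.11.5 and were kept unless stated.

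Between the 2 HMEC populations, held-out counts were summed per lane and population and tested with edgeR 4.0.16 (quasi-likelihood test, TMM, filterByExpr), under R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. The lanes are technical replicates, so these p-values measure only the spread between lanes. Each lane gave 1 sum to each population, so the sums pair by library. After deviations from the population mean were taken over 2036 rows, sums of the same lane correlated at 0.509, 0.306 and 0.267 for lanes 1, 2 and 3, each above 0.1. The test without the lane as a factor was fixed as the main one. Simulated counts with 50 rows changed at each fold tested this step on 5609 rows for this comparison. It recovered 34% of the 1.25-fold changes, 78% of the 1.5-fold changes and 100% of the 2-fold changes, with 10 false calls (6.02% of calls). Changed rows were drawn only from rows above a minimum expected count, so recovery among rows of lower counts was not measured. The sums were simulated as independent at 1 dispersion (0.00293), without the correlation of same-lane sums.

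All other comparisons were fixed as values without a test, with each pooled matrix as 1 sample. For the original HMECs, counts summed over barcodes of each of the 3 column parts were also tested against the 3 lanes with the same edgeR steps, on all human rows. The parts were taken as lanes of 1 experiment, so these p-values, too, measure only the spread between lanes. Parts of the cell mixture and of the nuclei were not tested. In the comparisons of values, rows were counted by fixed rules of size: at least 10 CPM (counts scaled to a library sum of 1e+06) on 1 side, and a fold of 2 against every lane for the original HMEC experiment or a fold of 4 between populations of 1 matrix. At most 2 rows in each direction were named per comparison: those with the largest fold among rows of at least 100 CPM on the higher side that changed alike in every lane. Shares carry exact binomial 95% intervals and summed counts exact Poisson 95% intervals, and both cover counting error only. Profiles were compared by Spearman's rho or Pearson's r of log2(CPM + 1). Such correlations run across rows, which are not independent replicates.

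Depth set the precision. The 3 technical-replicate lanes held between 16047918 and 19835711 UMIs each, the original HMEC matrix 809849691, the cell mixture 334602886, the nuclei 26473164, and the PDX 2830404 on human rows and 35122405 on mouse rows. Alternatives covered the UMI minimum, row filter, pseudocount, clustering, purity, thinning depth, test and each lane left out; the named alternatives were fixed before the data were examined except for 6 added afterwards. DESeq2 1.42.0 was the alternative test. Scrublet called 0.0483%, 0.0103% and 0.0212% of barcodes in HMEC lanes 1, 2 and 3 and 0.0223% on PDX mouse rows. Rates under 0.5% in matrices of this size mean that the caller did not work there. On PDX human rows it called 0.384% of only 521 barcodes, which is no better evidence that it worked. Doublets in all these matrices are unresolved.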

Results

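The RNA data comprised 8 count matrices from 4 experiments. HEK cells, a human embryonic kidney line, were mixed with human mammary epithelial cells (HMECs), which are cultured cells of the breast epithelium. A second mixture was profiled as nuclei. HMECs were profiled in an original experiment and in technical-replicate lanes, of which 3 were analysed. A patient-derived xenograft (PDX) gave human and mouse cells. At the minimum of 500 UMIs, lanes 1, 2 and 3 of the HMEC technical replicate held 10352, 9723 and 9448 barcodes, with medians of 1106, 897 and 901 UMIs. The original HMEC matrix held 45715 such barcodes with a median of 13064 UMIs. Of these, 29167 held at least 2000 UMIs, with a median of 23978. The barcode at rank 100000 of this matrix still held 416 UMIs, so the 45715 may include barcodes without a cell. The cell mixture held 24614 barcodes (median 13588 UMIs) and the nuclei mixture 11369 (median 1054 UMIs). The PDX held 521 barcodes on human rows (median 1279 UMIs) and 8963 on mouse rows (median 3349 UMIs). Barcodes below the minimum held 35.6%, 39.9% and 43.2% of the UMIs in HMEC lanes 1, 2 and 3, 43.4% in the nuclei, 48.6% on PDX human rows, 10.9% on PDX mouse rows, 9.92% in the original HMECs and 6.43% in the cell mixture.

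**Figure D1:**
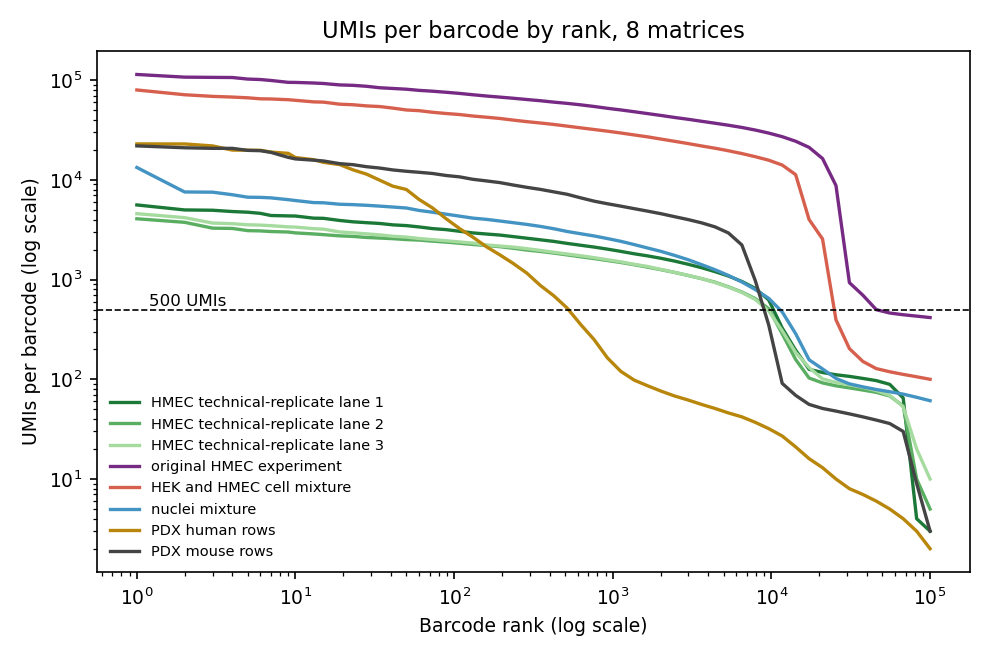
UMIs per barcode (log scale) against barcode rank (log scale), 1 line per matrix, with the minimum of 500 UMIs dashed. The original HMEC line passes the minimum on a shallow slope, where 45715 barcodes reach 500 UMIs and 29167 reach 2000 UMIs.

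At a common depth of 2000 UMIs per barcode, nuclei had the most detected rows, with a median of 1322.5. HMECs of lanes 1, 2 and 3 had medians of 839, 856.5 and 857 rows, the original HMECs 974, the cell mixture 916, PDX human rows 876.5 and PDX mouse rows 927. Before thinning, the same barcodes had medians of 951, 937.5 and 938 rows in HMEC lanes 1, 2 and 3, 4632 in the original HMECs, 3484 in the cell mixture, 1625 in nuclei, 1472.5 on PDX human rows and 1419 on PDX mouse rows. The depth left out 9384, 9449 and 9136 barcodes of lanes 1, 2 and 3, so their values rest on 968, 274 and 312 barcodes. It left out 16548 barcodes of the original HMECs, 2884 of the cell mixture, 9541 nuclei, and 351 and 2175 barcodes on PDX human and mouse rows. Nuclei were counted on rows of both organisms.

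The technical-replicate lanes asked how far repeated runs of the HMEC experiment differ. HMEC expression was alike across the 3 lanes, with a mean Pearson's r of 0.9957 over 3 lane pairs and 18846 rows. The lanes were not copies of each other: their summed counts differed by more than sampling noise in every pair, with chi-square values per degree of freedom of 5.25, 4.07 and 1.62. With the original HMEC experiment, r was between 0.9876 and 0.9882 over 24485 rows, a different set of rows. The order of these r values depended on the pseudocount: at 0.1 CPM the mean was 0.9844 between lanes and 0.9859 with the original. Spearman's rho, which a pseudocount does not change, was between 0.9619 and 0.9629 between lanes and between 0.9363 and 0.9404 with the original over all human rows.

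By the rule of size, 290 of 7725 rows differed at least 2-fold between the original HMECs and every lane, 228 higher and 62 lower in the original. Row 5047 was at 1615 CPM in the original HMECs and 209.9 ± 22.7 CPM in the lanes (SD, n = 3). Row 15778 was at 102.4 CPM in the original and 23.9 ± 1.497 CPM in the lanes. In the other direction, row 1961 was at 5.07 CPM in the original and 136.2 ± 3.29 CPM in the lanes, and row 20352 at 150.9 CPM and 671.8 ± 29.8 CPM. These differences were larger than the spread between lanes. The 3 column parts of the original were then taken as its lanes, a choice made after the data were seen. All 290 rows passed an edgeR quasi-likelihood test in the same direction (Benjamini-Hochberg adjustment at 0.05), but 191 of them were 2-fold apart in its fit. The 290 rows had been chosen by size from these same counts, so their passing is not independent support. Of all 16763 rows tested, edgeR called 8450 (50.4%). Of these, 1477 differed at least 2-fold, 685 higher and 792 lower in the original. Among the 7725 rows of the rule of size, it called 280 that differed at least 2-fold, 129 higher and 151 lower. With the scaling alone changed from CPM to TMM, a log2 shift of -0.22, the rule of size gave 216 rows, 105 higher and 111 lower in the original, and 167 of them were among the 290. The larger number of higher rows under CPM therefore depended on the scaling. The parts and lanes also differ in experiment and depth, which the test cannot separate from any other difference. Under CPM, the count rose to 1396 of the 7725 rows at a fold of 1.5. At a minimum of 50 CPM it was 95, but of only 2631 rows. Of the rows higher in the original, 138 (60.5%) lay at least 2-fold above both HMEC populations described next, and 23 of those lower in the original (37.1%) lay at least 2-fold below both.

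HMECs of the technical replicate fell into 2 main populations in every lane. Population 1 held 60.9% ± 1.38 of barcodes and population 2 held 38.9% ± 1.31 (SD, n = 3 lanes). Population 1 made up 59.4% of lane 1 (58.4 to 60.3, exact binomial 95% interval), 62.0% of lane 2 (60.98 to 62.92) and 61.5% of lane 3 (60.5 to 62.5). The other 49 barcodes formed a small separate cluster. Population 1 was the deeper, with median UMIs of 1062 ± 149 against 825 ± 92.5 (SD, n = 3 lanes). At 500 UMIs per barcode it had 317 ± 3.51 detected rows, against 323 ± 3.51 in population 2. Clustering on even-numbered rows placed 93.6% of 29474 barcodes alike. A minimum of 1000 UMIs gave a population 1 share of 73.2%, and a resolution of 0.4 divided that population into 10349 and 7799 barcodes.

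**Figure D2:**
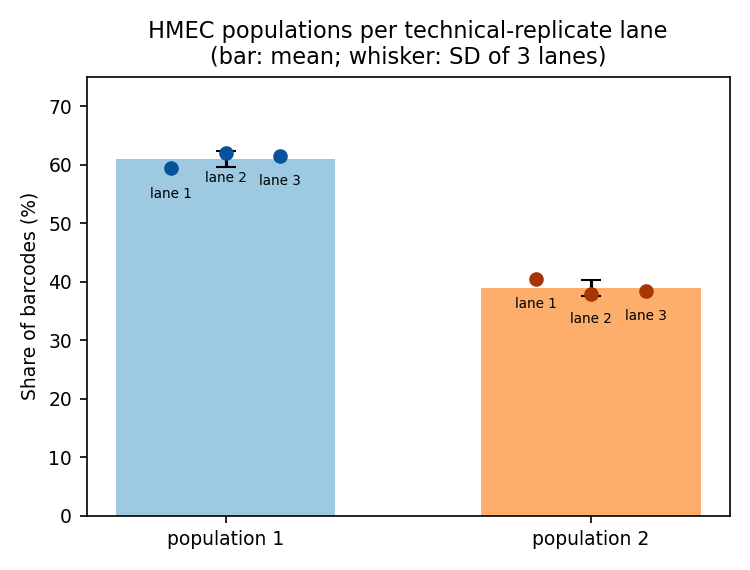
Share of barcodes (%) in HMEC populations 1 and 2. Bars are means over 3 technical-replicate lanes, whiskers are SDs and points are lanes. Population 1 lies between 59.4% and 62.0% in all 3 lanes.

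Among rows held out of the clustering, 2546 of 5677 differed between the HMEC populations (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment at 0.05), 1252 higher and 1294 lower in population 1. Of these, 719 differed at least 2-fold, 279 higher and 440 lower in population 1. Row 1308 was at 119.6 ± 4.96 CPM in population 1 and 18.3 ± 1.26 CPM in population 2 (SD, n = 3 lanes), a log2 fold change of 2.80 (SE 0.11, edgeR adjusted p = 4.37e-15). Row 12188 was 2.58 higher on the log2 scale in population 1 (SE 0.11, edgeR adjusted p = 5.00e-14). Population 2 was marked by row 15510, at 150.3 ± 3.37 CPM against 7.97 ± 0.662 CPM in population 1 (log2 fold change -4.12, SE 0.11, edgeR adjusted p = 1.13e-17), and by row 23814, at 337.1 ± 39.9 CPM against 18.3 ± 1.21 CPM (log2 fold change -4.10, SE 0.11, edgeR adjusted p = 1.09e-17). All 4 rows had the same direction in 3 of 3 lanes. With barcodes thinned to 2000 UMIs, 524 of 1980 rows differed. The p-values measure the spread between lanes of 1 experiment, not between cultures or donors.

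The mixture of HEK cells and HMECs was used to compare tagging reagents, but its barcodes were not matched to reagents here. Its 2 k-means populations held 16514 barcodes (67.1%, exact binomial 95% interval 66.5 to 67.7) and 8100 barcodes (32.9%, 32.3 to 33.5). Population 1 was the shallower, with a median of 5722 UMIs against 16899 in population 2. Population 2 was nearer to the HMEC lanes, with a rho of 0.935 ± 0.00159 against 0.878 ± 0.00133 for population 1 (SD, n = 3 lanes). Between them, 946 of 8175 rows were at least 4-fold higher and 267 at least 4-fold lower in the HMEC-nearer population. No rows were held out of this clustering, so the counts describe the grouping and do not test it. The balance of higher and lower rows under a scaling other than CPM was not tested. Of the higher rows, 99.9% were also higher in every HMEC lane than in population 1, and 99.3% of the lower rows were lower in every lane. Population 1 entered both comparisons and no other profile was set beside these shares, so they are not independent evidence of HMECs. Row 2753 was at 1037 CPM in the HMEC-nearer population, 25.5 CPM in the other and 762.6 ± 51.1 CPM in the HMEC lanes. Row 8877 was at 465.2, 11.2 and 185.1 ± 31.0 CPM in the same order. Row 23406 was at 48.7 CPM in the HMEC-nearer population, 932.3 CPM in the other and 9.44 ± 0.904 CPM in the lanes, and row 14263 at 12.9 and 254.3 CPM with no count in any lane. The HMEC-nearer share was 28.0%, 30.7% and 43.3% in the 3 column parts, and it was 43.5% without a low-depth cluster of 5992 barcodes described among the other observations. A further low-depth Leiden cluster (cluster 6, resolution 0.1, median 766 UMIs) had a rho of 0.912 with the lanes, against 0.872 for cluster 1. Only 27.0% of its 1217 barcodes lay in population 2, so population 1 cannot be taken as free of HMECs.

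**Figure D3:**
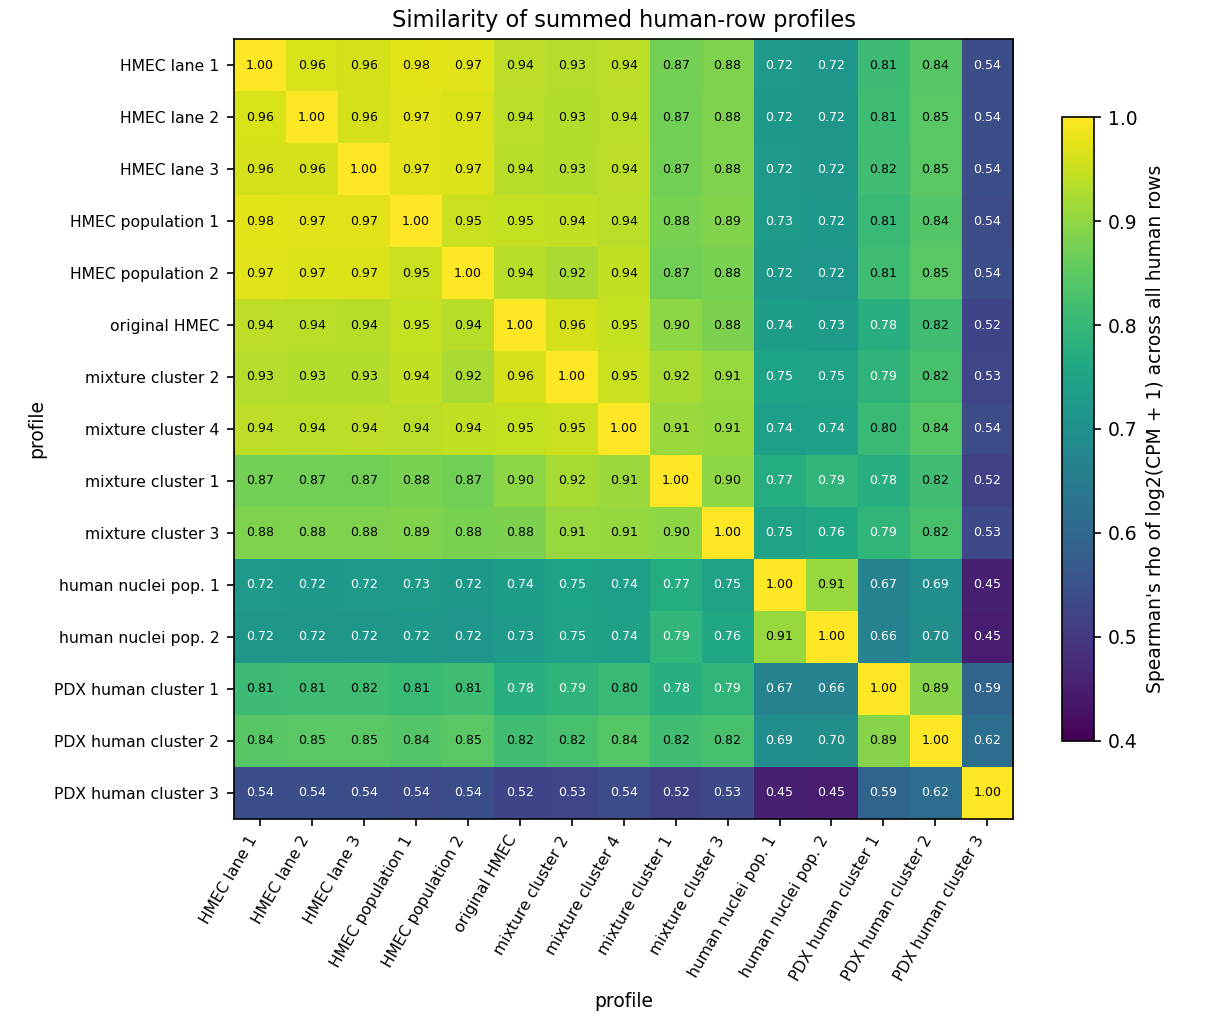
Spearman's rho of log2(CPM + 1) across all human rows between summed profiles of HMEC lanes and populations, the original HMECs, Leiden clusters of the cell mixture, human nuclei and PDX human clusters. Lanes lie at 0.96 to each other, mixture clusters 2 and 4 at 0.93 to 0.94 to the lanes, and PDX human cluster 3 at or below 0.62 to every other profile. The profile of PDX human cluster 3 sums only 50618 UMIs, so its values were not separated from low depth.

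The labels of the nuclei mixture differ on 1 of the cell types, and the matrix was used to ask whether mouse RNA was there. Human nuclei numbered 9063 (79.7%, exact binomial 95% interval 79.0 to 80.5), mouse nuclei 1855 (16.3%, 15.6 to 17.0) and mixed barcodes 451 (3.97%, 3.62 to 4.34). Its first row block matched PDX human rows at a rho of 0.712 and its second block matched PDX mouse rows at 0.776; with the blocks exchanged, the values were 0.00238 and -0.0159. The median human nucleus had 955 UMIs with 3.26% on mouse rows, and the median mouse nucleus 1889 UMIs with 3.52% on human rows. The mixed share was 1.86% at a purity of 80% and 20.4% at 95%, and the mouse share was 26.5% at a minimum of 1000 UMIs. In the 2 column parts, human nuclei made up 77.3% and 81.7% and mouse nuclei 18.4% and 14.6%. These values lie outside the intervals above, which cover counting error only.

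**Figure D4:**
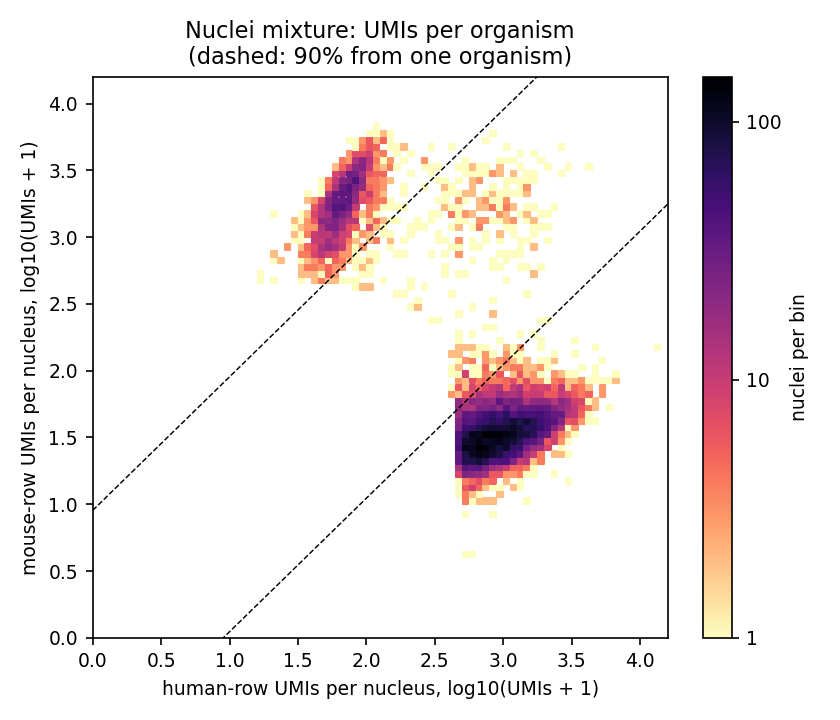
UMIs per nucleus on human rows (horizontal, log10(UMIs + 1)) and on mouse rows (vertical, log10(UMIs + 1)), coloured by nuclei per bin, with dashed lines at 90% purity. The 9063 human and 1855 mouse nuclei form separate groups, with 451 mixed barcodes between the lines.

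Human nuclei, for which the labels name HEK and Jurkat, a T-cell line, were divided by k-means into 7383 nuclei (81.5%, exact binomial 95% interval 80.6 to 82.3) and 1680 nuclei (18.5%, 17.7 to 19.4). Both populations were set against the k-means population of the cell mixture that lay farther from the HMEC lanes, at rho 0.772 and 0.792. With the HMEC lanes the values were lower, at 0.721 and 0.718. The lanes are shallower than the cell mixture, and against the HMEC-nearer population of that mixture the values were 0.747 and 0.749. Of 11683 rows, 601 were at least 4-fold higher in population 1 and 1566 in population 2. No rows were held out of this clustering, so these counts and the rows named next describe the grouping and do not test it. Their balance under a scaling other than CPM was not tested. Row 31421 was at 130.5 CPM in population 1 and 6.43 CPM in population 2, and row 27513 at 153.2 and 10.1 CPM. Row 7367 was at 14.3 CPM in population 1 and 1563 CPM in population 2, and row 22304 at 8.80 and 969.1 CPM. With 3 groups, the 2 larger ones held 48.1% and 33.5% of human nuclei and the smallest 18.4%, near the share of population 2. With 2 groups, population 1 held 78.1% and 84.1% of human nuclei in the 2 column parts, outside its interval of 80.6 to 82.3.

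The PDX was described by organism. Mouse cells made up most of its barcodes, 8963 against 521 on human rows. Barcodes with at least 500 UMIs on human rows formed 3 clusters of 365, 92 and 64 barcodes. Of the 521, 90 (17.3%, exact binomial 95% interval 14.1 to 20.8) also held at least 500 UMIs on mouse rows, 48, 23 and 19 of them in clusters 1, 2 and 3, and the median human share of UMIs in these 90 was 30.01%, so not all can be taken as human cells. The rho of clusters 1, 2 and 3 with the HMEC lanes was 0.814 ± 0.00206, 0.846 ± 0.00116 and 0.544 ± 0.000353 (SD, n = 3 lanes). These SDs cover the spread between lanes only. The cluster profiles summed 665729, 737792 and 50618 UMIs, so the low rho of cluster 3 was not separated from its low depth. Human cluster 2 was the deepest, with a median of 7542.5 UMIs, and in human cluster 3, with a median of 661 UMIs, 50 rows took 71.1% of UMIs. Mouse cells formed 13 clusters, the largest with 3834 barcodes (42.8%, exact binomial 95% interval 41.7 to 43.8), followed by clusters of 1529 and 819 barcodes. At a resolution of 0.4, 5 human and 18 mouse clusters were found.

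Scrublet called 4.81% of the original HMEC barcodes of at least 2000 UMIs, 3.10% of the cell mixture and 2.09% of the nuclei as doublets. It called 28.4% of the 451 mixed nuclei. On PDX human rows it called 2 of 521 barcodes (0.384%), and in the HMEC lanes and on PDX mouse rows it did not work, so doublets are unresolved in all of these.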

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

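The test of bead abundance was chosen only after the result was seen. Barcode columns that held a cell in 1 library carried extra UMIs in other libraries, a signal outside the main comparisons. At the cell columns of HMEC lane 1, lane 2 held an excess equal to 3.239% of the lane 1 UMIs. This was the largest of 6 ordered lane pairs, whose mean was 1.21% and whose lowest value was 0.0447% (SE 0.0381). The parts of the original HMEC matrix held a mean excess of 0.6682% at each other's cell columns. PDX human rows held an excess of 1.118% of nuclei UMIs at columns of human nuclei. In simulated data with an exchange of 0.7%, the same step recovered 0.704%.

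For these columns, bead barcodes abundant in every run are argued against by the cell mixture, whose parts showed a mean ratio of 1.0072 between cell columns and other columns. Reads assigned to the wrong library remain a candidate explanation: as a percent of the nuclei's own UMIs, the excess on PDX human rows was 44.125 times larger at human than at mouse nuclei (12.9 against 0.530 UMIs per column, SE 0.143 and 0.204), which a property of the column alone would not give. This may also have lifted original HMEC barcodes past the minimum, since 21.108% of the 16548 barcodes of 500 to 2000 UMIs sat at columns with a cell in another part, against 2.62% by chance. The remaining barcodes of that range are not accounted for by this. In the original matrix, UMIs fell only from 499 at rank 45816 to 416 at rank 100000, so the minimum of 500 lay at the edge of a plateau. Barcodes just above it may hold no cell, which was not tested. No biological explanation was tested.

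On PDX columns, 90 reached 500 UMIs on both human and mouse rows, against 6.33 by chance. They were 17.3% of the barcodes with 500 UMIs on human rows, and their median human share of UMIs was 30.01%.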

How the results depend on the processing

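Tests of the original HMECs as column parts (by size and with edgeR), of TMM scaling in the rule of size, original barcodes of at least 2000 UMIs, barcodes placed alike by odd and even rows, and the cell mixture without its cluster 3 were chosen after the data were seen. Of the alternative values, 73 were counted as the same and 60 as moved. The 73 include all 36 alternatives of the 4 named rows, which were judged only by direction and threshold. The other values were judged by their spread or by a factor of 1.5. No single value changed sign, but the order of 2 agreements turned: with a pseudocount of 0.1 CPM, the mean r was higher with the original than between lanes. The balance of rows higher and lower in the original also turned, from 228 and 62 by CPM to 105 and 111 with TMM scaling alone. The 4 rows named between the HMEC populations kept their direction and stayed past the threshold in all 36 alternatives that gave them a value, the highest edgeR or DESeq2 adjusted p being 2.83e-07. The count of held-out rows was between 2038 and 2152 when each lane was left out, 1745 with DESeq2 and 2581 on odd-numbered rows, and it fell to 524 with barcodes thinned to 2000 UMIs, where 1980 rows were tested on fewer barcodes. With the lane as a block, 2875 rows differed, and 2543 of the 2546 main calls were among them; the block moved no count by more than 1.5 times. Split into 10 groupings of the 6 sums, the edgeR test gave 2546 rows for the real split and 0 for the highest other (2883 and 103 at an unadjusted p under 0.05); among the 4 splits that part every lane pair, the highest other gave 0 (52 unadjusted). With 10 splits, 1 of which gave as many rows, no share under 0.05 can be reached. Every other split also mixes both populations in each group, so their difference becomes spread within groups. Few calls follow there by construction, and no conclusion is drawn from the contrast of 2546 with 0.

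Barcode counts followed the UMI minimum. At 1000 UMIs they were 6107, 3842 and 3840 in HMEC lanes 1, 2 and 3, 6096 in nuclei and 321 on PDX human rows. At 2000 UMIs they were 968, 274 and 312 in the lanes, 29167 in the original HMECs, 1828 in nuclei and 170 on PDX human rows. With no minimum they were 294634, 313358, 332981, 2065124 (original), 1390955 (cell mixture), 587606 (nuclei), 222390 (PDX human) and 357102 (PDX mouse). Detected rows followed the thinning depth by construction: at 1000 UMIs 521, 532 and 526 in the lanes, 579 in the original, 549 in the cell mixture, 766 in nuclei, 517 on PDX human rows and 567 on PDX mouse rows; at 4000 UMIs 1309 in lane 1, 1593, 1523, 2155, 1432.5 and 1480 in the same order. Lanes 2 and 3 had too few barcodes for 4000 UMIs.

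The mean r between lanes was 0.995381 over rows of at least 10 CPM, 0.984432 with a pseudocount of 0.1 CPM and between 0.995684 and 0.995765 with a lane left out; with the original it was 0.961088 and 0.985869. Rows differing from the original numbered 1396 at a fold of 1.5, 95 of 2631 at 50 CPM and 1477 with edgeR on the parts, which had no minimum of 10 CPM. Among the 7725 rows at 10 CPM or more, the edgeR count was 280, near the 290 of the rule of size. Of 10 splits of the 3 parts and 3 lanes, 1, the real one, gave as many as 1477 rows. The highest other gave 0 in edgeR (1641 and 11 at an unadjusted p under 0.05). The other splits mix parts and lanes in each group, so few calls follow there by construction. No share under 0.05 can be reached, and no conclusion is drawn from these splits. At a resolution of 0.4, HMEC population 1 was divided: its larger piece held 35.1% of barcodes, and the pieces of 10349 and 7799 barcodes lay to 98.6% and 98.7% in population 1. The share of population 1 was 67.0% by k-means, 73.2% at 1000 UMIs and between 60.1% and 62.6% with a lane left out. The HMEC-nearer share of the cell mixture was 36.9% with joined Leiden clusters, 35.1% at 1000 UMIs and 43.5% without cluster 3. Human, mouse and mixed nuclei were 81.1%, 17.1% and 1.86% at 80% purity and 66.5%, 13.0% and 20.4% at 95%; human and mouse nuclei were 69.3% and 26.5% at 1000 UMIs. With 3 groups of human nuclei the largest held 48.1% and the next 33.5%, while the smallest, at 18.4%, was near population 2 (18.5%); at 1000 UMIs population 1 held 77.4%. PDX human clusters numbered 5 at a resolution of 0.4. Where not stated, the cause was not tested. The Scrublet alternative removed few barcodes in the HMEC lanes, where the caller did not work, so it says little there. Low depth limits the HMEC lanes, the nuclei and the PDX human rows most.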

Other observations

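The tests of low depth, of doublets and of the nuclei label were chosen only after the result was seen, as were the Leiden clustering of the nuclei and the use of free RNA shares against the test of missing rows. The tests against nuclei population 1, of a free RNA floor and of missing rows after free RNA was taken off were written before their own values but after the other tests of that cluster were seen. Free RNA was taken as the summed profile of 117793 barcodes of the cell mixture with at least 10 and under 100 UMIs.

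Cells of other HMEC samples were assigned to both HMEC populations of the lanes. A classifier trained on the lanes, which placed 93.2% to 93.3% of barcodes of a left-out lane as the clustering had, assigned 68.9% of original HMEC barcodes of at least 2000 UMIs (68.4 to 69.4, exact binomial 95% interval) to population 1. The column parts of the original gave 68.4%, 67.9% and 70.5%. Left-out lanes 1, 2 and 3, at a minimum of 500 UMIs, gave 56.6%, 59.4% and 59.8%. By clustering, the lane share rose to 73.2% at a minimum of 1000 UMIs. The original barcodes held at least 2000 UMIs, so a difference in composition cannot be told apart from depth. Within the HMEC-nearer cells of the mixture, thinned to 500 UMIs, cluster 2 was assigned to population 1 for 96.4% of 6165 barcodes and cluster 4 for 9.59% of 1418. The classifier assigns every barcode to one population or the other, so these shares do not show that no further population was there.

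Leiden clustering of the cell mixture at a resolution of 0.1 gave a cluster (cluster 3) of 5992 barcodes (24.3%) with a median of 3438.5 UMIs and 636 detected rows at 2000 UMIs, against 930 in cluster 1. Low depth of the main non-HMEC cells is argued against by 916 rows at least 4-fold from cluster 1 (3 in cluster 5, at 974.5 UMIs). Doublets of HMECs with another cell are argued against by the median of 3438.5 UMIs, far under the 16835 and 17376 of clusters 1 and 2. For cells of the kind of nuclei population 1, differences from cluster 1 were correlated with the difference between the nuclei populations. The rho was 0.03541, below the 0.1413 of cluster 2, which the bound written for it read as against such cells. No matched cells and nuclei were at hand to show what rho a match would give, so this explanation stays undecided. Mouse cells counted on human rows and a further human cell type or state also stay open. Of 568 widely used rows, 0 (0%) were below 10 CPM, which the bound written beforehand read as against mouse cells, but free RNA alone could hold rows there: its share of the cluster was estimated at 2.2% from the mean of 75.65 UMIs in an empty barcode and at 7.45% to 12.49% from rows specific to other clusters, which overestimate it if cluster 3 uses those rows. At 2.2%, 7.45% and 12.49%, free RNA would hold 48.1%, 96.3% and 99.65% of the rows at 10 CPM or more, and once it was taken off 0.352%, 5.81% and 18.31% of them were below 10 CPM, so none passed the bound of 20% written for mouse cells and only the lowest share gave a value under the opposing bound of 5%. Ratios to free RNA that pile up at a low floor were predicted for mouse cells with free RNA: the 25th percentile of log2 ratios was -2.57, below the bound of -1.5 that clusters 1, 2 and 4 did not reach (-0.522, -0.692 and -0.882), but the 25th minus 5th percentile was 0.9148, between the bounds of 0.5 and 1, and clusters 1, 2 and 4 gave 3.33, 0.587 and 0.733, so this spread does not mark human clusters; the 50 rows most raised in the cluster were at 1.06385 times their human-nuclei level in mouse nuclei (0.978 to 1.16), above the bound of 1 written for mouse cells but with an interval that includes it. Damaged cells were not tested, and no explanation for the cluster is favoured by these values.

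The cell type label of the nuclei names HMECs where the source label and the design text name MEFs. Mouse nuclei made up 16.3%. For human nuclei, rho with the HMEC lanes was compared with rho with the cell mixture population farther from those lanes. The largest difference was -0.01118 over 12 human populations and settings, so none lay nearer to the HMEC lanes. With the HMEC-nearer population of the mixture in place of the lanes, the largest difference was -0.01405. These values are consistent with mouse cells in the place of HMECs. Nuclear and cellular RNA differ, and no HMEC nuclei were at hand to show what difference they would give, so a small HMEC share is not excluded. With mixed nuclei taken as human and mouse doublets at random, 3.97% mixed implies a doublet rate of 14.1%. The mixed barcodes had a median of 1223 UMIs, below the 1889 of mouse nuclei, so not all of them need be doublets. At a purity of 80% the mixed share was 1.86% and the median 2293 UMIs, so the 14.1% may be too high.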
